A study of Mus musculus with 6 samples.

How the data were processed

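Per the labels, 6 single-nucleus RNA libraries came from mouse hippocampus, 3 titled control and 3 titled IH. The series title sets POSA mice against controls kept in normal oxygen, and the design line names pediatric OSA. The letters IH are not spelled out, and exposure, age, sex and strain are not given in the sources used here. The extraction text speaks of dissociated gliomas and single cells, whereas the tissue field and the design line give hippocampus and single nuclei. The labels do not say that the libraries are separate animals, so every p-value measures only the spread between these samples.

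Each deposited matrix holds raw UMI counts per gene and barcode, per the file headers, with no normalization. The matrices were made with Cell Ranger 8 and a 10x Genomics 3' kit against the mm10 genome, per the submitters' processing notes. The annotation release, the cell-calling settings and any pooling of samples are not given in the sources used here. The matrices list 31055 features, of which 71 carry a symbol shared with another feature. Gene positions were taken from GENCODE vM21 on GRCm38, the assembly also called mm10.

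The libraries held 149072524 to 171487583 UMIs in 22094 to 31957 barcodes. Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were retained, 152557 of 158186. Scrublet's automatic threshold marked 0 to 2 barcodes in each library except IH 2, where it marked 4868 or 18.5%, so the planned use of that threshold was replaced after its calls were seen. The highest doublet scores were marked instead at an assumed 0.4% per 1000 barcodes, 16306 in all, together with whole clusters whose mean score reached 0.08. In total 34858 barcodes or 22.8% were marked and 117699 nuclei were kept, 17281 to 22930 per library. Kept nuclei held 100574186 to 113888783 UMIs per library, and the library medians were 3108 to 4263 UMIs and 1576 to 1963 genes per nucleus.

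Nuclei of all libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Counts scaled to 10000 per nucleus gave 2000 variable genes, 30 principal components, 20 neighbours and a Leiden resolution of 1, with seed 1. A cluster of at least 30 nuclei was named where at least 3 markers of a class stood 2-fold above the other clusters at 10 CPM or more, with a pseudocount of 10 CPM, together with a rule on its 10 strongest genes. The naming rule went through 3 forms, each judged on the clusters and before any comparison of the groups. The form used left gene models without a functional name out of the 10 strongest genes. The form before it kept them and named 27 instead of 28 clusters, with the oligodendrocyte-like nuclei, 15991 before all doublets were removed, left unnamed. Clusters with 3-fold raised ribosomal protein transcripts were kept apart from their classes, after their shares were seen to vary between libraries. Each class is called by its markers, so "astrocyte-like" stands for nuclei with astrocyte markers. The 16 named classes with at least 50 kept nuclei in every library were compared.

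Samples were grouped by their titles into 2 groups of 3, and the library was the replicate. UMI counts were summed per library, over all kept nuclei and per class, and compared with the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3, with TMM scaling, filterByExpr and a Benjamini-Hochberg threshold of 0.05. Fold changes are log2 of IH over control, with a standard error (SE). Differences of the condition effect among classes were tested with an edgeR F test of the class by condition interaction, with the library as block. Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01. That family held 318 pairs of list and class, and camera with an estimated correlation and fry were alternatives. Shares of nuclei and medians per nucleus were compared with an exact permutation test, two-sided, whose smallest p with 3 against 3 is 0.1. Genes per nucleus were also compared after every nucleus was thinned to 1000 UMIs.

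The grouping, these tests, the marker genes, the gene lists, most alternatives and the rule for naming genes were set before the data were examined. That rule named, past the threshold, the genes with the largest fold at 20 CPM or more without overlap between the groups. Where none passed, it named the 3 genes with the smallest p per comparison, leaving out gene models and sex-linked genes. It also set 8 genes to report in any case, namely Vegfa, Slc2a1, Hif1a, Epas1, Hif3a, Gfap, Fos and Bdnf. For each gene list called, up to 4 members with the smallest p were eligible for naming, and likewise for HIF targets, glycolysis, immediate early genes and mitochondrially encoded genes whether called or not.

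The tests were checked on simulated counts with the depth of these libraries and a spread set by edgeR's fitted trend of dispersion with expression level. Spread of single genes around that trend and differences between library series, sexes or dissections were not simulated. Recovery in the real libraries can therefore be lower than the figures given here. Over all kept nuclei edgeR recovered 13 of 67 genes changed 1.5-fold, 46 of 67 changed 2-fold and 63 of 66 changed 4-fold, with 5 false among 127 calls. In the dentate class the same figures were 20, 51 and 61, and in the ependymal class 3, 32 and 48. Camera called 0 of 313 lists without a simulated change, and a list shifted 1.25-fold passed in 16 of 17 comparisons. The simulated genes were drawn independently, so this leaves the correlation between genes untested, and in the other splits of the real libraries camera called 45 to 88 pairs. The interaction test recovered 15, 59 and 66 genes, with 4 false among 144 calls.

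Xist and Y-linked counts showed control 2 and IH 2 to be female and the other 4 libraries male, so sex was balanced between the groups. The library names fall into 3 series. Control 1 and IH 3 share a plain prefix, controls 2 and 3 have the prefix Q1, and IH 1 and IH 2 have Q2. The Q1 and Q2 series each hold 1 group only, so a fit with 3 series rests on control 1 against IH 3. Without control 1, or without IH 3, no series holds libraries of each group, so group and series cannot be told apart in those settings. No label says that the replicate numbers pair the samples. After removal of the group means, control and IH libraries of the same number correlated across genes at 0.15, 0.33 and -0.12 over all kept nuclei and at 0.25, 0.20 and 0.07 in fibroblast-like nuclei. Control 1 and IH 3, of unlike number but the same prefix, correlated at 0.36 in dentate, 0.37 in CA1 and 0.36 in CA2/CA3 nuclei. They stood at 0.13 over all kept and -0.08 in fibroblast-like nuclei. Control 2 and IH 2, which share number and sex, reached 0.50 in dentate nuclei. A replicate block was run only as an alternative.

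Other alternatives were DESeq2 1.42.0 with its own filter, RLE size factors, no filter on low counts, each library left out in turn, the library name series as a term, doublets kept, at least 1000 detected genes, at most 2% mitochondrial UMIs, equal nuclei per library, a fold of at least 1.5, and a Leiden resolution of 0.5. Chosen after seeing the data were a 3-level series term, sex as a term, robust dispersion moderation, ribosomal-protein-rich clusters merged into their classes, and shares with other denominators. The counts under robust moderation were seen before those under the planned default. Unnamed clusters, choroid plexus, mossy and perivascular macrophage nuclei were left out of the gene tests, the unnamed ones for want of a class and the others for too few nuclei in some library.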

Results

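The hippocampus forms and recalls memories of place and events, and sleep apnea in children has been linked to poorer learning. The question behind the libraries was how hippocampal cells of the IH group differ from those of controls. Here 117699 kept nuclei from 3 control and 3 IH libraries were compared by cell class, by gene and by gene list.

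The first comparison asked whether the cellular make-up of the tissue differed. Inhibitory neurons, immature neurons and newly formed oligodendrocytes took a larger mean share of the IH nuclei, and ependymal cells, the ciliated lining of the ventricle, a smaller one. The large neuron classes and the main glial classes had overlapping shares in the groups. Inhibitory neuron-like nuclei made up 3.95% ± 0.185 of control nuclei and 5.11% ± 0.81 of IH nuclei (mean ± SD, n = 3 libraries per group, exact permutation test, two-sided, p 0.1). Immature neuron-like nuclei, marked by genes such as Dcx and Sox11, made up 0.94% ± 0.152 and 1.35% ± 0.0598 (exact p 0.1), and the groups overlapped among nuclei with at least 1000 detected genes (0.941% and 1.15%, exact p 0.3). Newly formed oligodendrocyte-like nuclei made up 0.57% ± 0.174 and 0.824% ± 0.177 (exact p 0.1). Ependymal-like nuclei made up 1.22% ± 0.0874 and 0.614% ± 0.209 (exact p 0.1). In these 4 of 16 classes the 3 IH libraries lay on one side of all controls, which chance gives for 10% of classes, and 0.1 is the smallest p that 3 against 3 allows. The count was 2 of 16 among nuclei with at least 1000 detected genes. It was 2 of 14 for shares of named classes without choroid plexus, ependymal and fibroblast nuclei. Dentate granule neuron-like nuclei made up 17.7% ± 0.307 and 19.7% ± 4.63, CA1 pyramidal neuron-like nuclei 6.8% ± 3.09 and 6.11% ± 2.39, and CA2/CA3 pyramidal neuron-like nuclei 3.69% ± 0.45 and 3.53% ± 0.8. Subicular or cortical excitatory neuron-like nuclei made up 2.56% ± 0.451 and 3.52% ± 1.18. Oligodendrocyte-like nuclei made up 13.7% ± 1.09 and 13.6% ± 2.81, astrocyte-like nuclei 12% ± 0.997 and 12.3% ± 2.82, and microglia-like nuclei 4.82% ± 1.67 and 5.29% ± 2.09. Oligodendrocyte precursor-like nuclei made up 2.75% ± 1.23 and 2.43% ± 0.501. Fibroblast-like nuclei made up 2.6% ± 0.384 and 1.64% ± 0.915, endothelial-like nuclei 1.97% ± 0.191 and 1.56% ± 0.81, and nuclei of pericyte or smooth muscle type 1.1% ± 0.158 and 0.934% ± 0.317. With nuclei counted per class, edgeR called 0 of 16 classes, and the ependymal-like class came nearest at a log2 fold of -0.99 (SE 0.32, adjusted p 0.0862). Within the plain-prefix series the ependymal-like share was 1.20% in control 1 and 0.458% in IH 3, and the inhibitory neuron-like share was 3.75% and 4.53%.

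**Figure D1:**
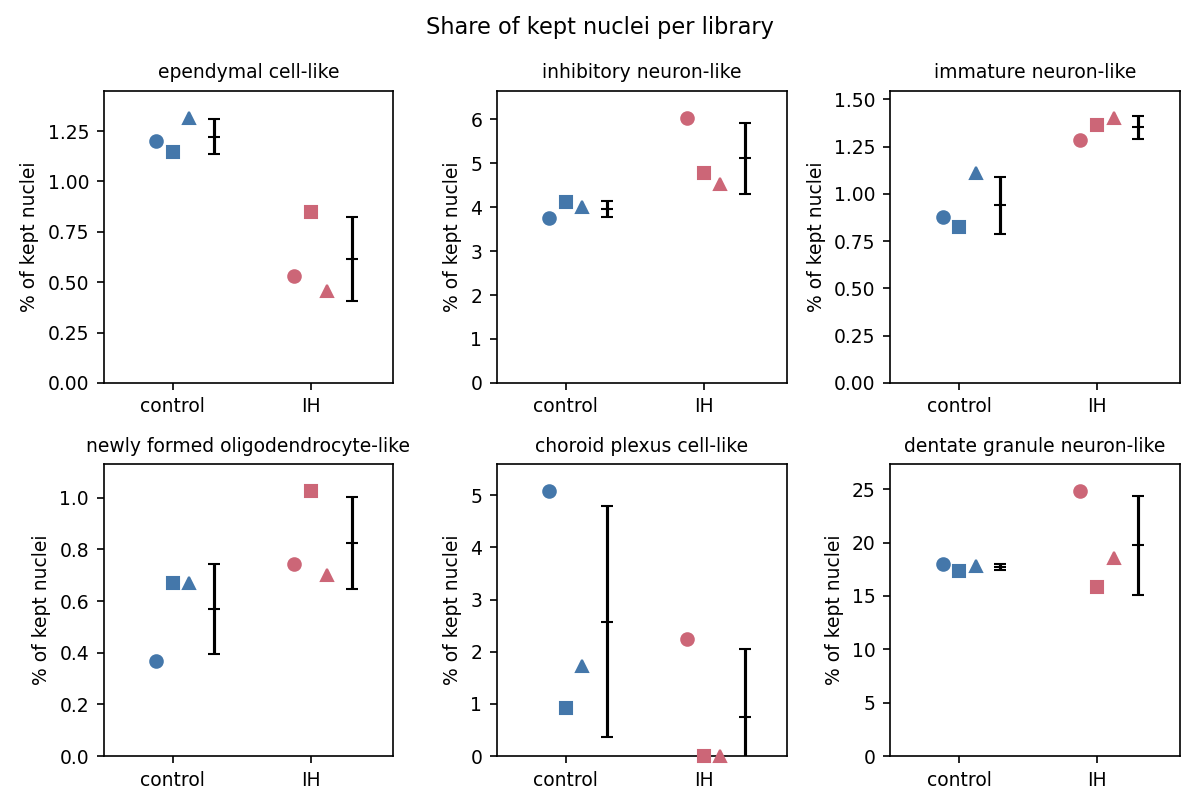
Share of kept nuclei (%, vertical axes) in 6 cell classes, with a point per library, control and IH side by side, and the mean ± SD of each group as a black bar. The ependymal-like share of the 3 IH libraries, 0.458% to 0.851%, lies below that of every control.

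The main cluster of choroid plexus cells, which make cerebrospinal fluid and express Ttr, had nuclei in 4 of the 6 libraries. It made up 2.57% ± 2.21 of control nuclei and 0.75% ± 1.3 of IH nuclei (mean ± SD, n = 3 per group, exact p 0.3). In this cluster IH 2 held 0 of 20453 nuclei and IH 3 held 0 of 22930, which by counting error alone allows shares of it of up to 0.0147% and 0.0131%. IH 1 held 439 such nuclei. A small cluster rich in ribosomal protein transcripts, kept apart, carried choroid plexus markers as well and held 8 nuclei in IH 2 and 24 in IH 3, so nuclei with these markers occurred in all 6 libraries.

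Depth per nucleus overlapped between the groups. The library median was 3991 ± 236 UMIs per nucleus in controls and 3610 ± 435 in IH (mean ± SD, n = 3 per group, exact p 0.5), and 1924 ± 63.5 and 1765 ± 168 genes (exact p 0.2). After thinning to 1000 UMIs the medians were 656 ± 5.51 and 658 ± 6.11 genes (exact p 0.6). The difference in median UMIs went from -382 to -131 without IH 2 and to -246 without control 2, and that in genes from -159 to -64.8 without IH 2. Mitochondrial transcripts took 0.359% of the UMIs in controls and 0.439% in IH (exact p 0.7), where IH 1 at 0.608% stood apart from IH 2 and IH 3 at 0.362% and 0.346%, and ribosomal protein transcripts 0.351% and 0.379% (exact p 0.7).

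The next comparison asked which genes differ in level between IH and control hippocampus as a whole. No gene passed the threshold, and the genes with the smallest p were transcription factors found at low levels. The low-oxygen genes set beforehand had mean fold changes near 0. With edgeR, 0 of 20166 genes passed, and DESeq2 called 82. An unadjusted p under 0.05, which chance alone gives to a share near 0.05, was found by edgeR for 1062 genes. Without control 1, 141 genes passed, whereas leaving out any other library gave 0. The controls left in that fit are all of the Q1 series, which holds no IH library. Those calls can therefore reflect the series as well as the group. Without IH 3 group and series cannot be told apart either, and there 0 genes passed. The cause of the 141 calls was not tested. Ebf2, a factor of maturing neurons, had 6.29 ± 2.32 CPM in controls and 0.658 ± 0.217 in IH (mean ± SD, n = 3 per group), a log2 fold of -3.25 (SE 0.37, adjusted p 0.297, lower in 3 of 3 IH libraries). Uncx, a homeobox factor, had a log2 fold of -3.24 (SE 0.38, adjusted p 0.297), and Gata3, a factor of midbrain inhibitory neurons, -4.09 (SE 0.54, adjusted p 0.467). A cluster with the thalamic markers Tcf7l2 and Prkcd, left unnamed, held 115, 294 and 437 barcodes in controls 1 to 3 and 25, 20 and 81 in IH 1 to 3 before doublets marked by score were removed. On GRCm38, Ebf2 lies on chromosome 14 from 67233292 to 67430918, Uncx on chromosome 5 from 139543494 to 139548179 and Gata3 on chromosome 2 from 9857078 to 9890034. Among the genes set beforehand, Vegfa, which drives vessel growth in low oxygen, had a log2 fold of -0.08 (SE 0.11), and the glucose transporter Slc2a1 -0.12 (SE 0.14). The oxygen-sensing factors Hif1a, Epas1 and Hif3a had log2 folds of 0.06 (SE 0.07), 0.00 (SE 0.18) and -0.10 (SE 0.18). For both Slc2a1 and Epas1, IH 1 lay above every control and IH 2 and IH 3 lay below. Gfap, the astrocyte filament, had -0.12 (SE 0.15). Fos, induced by neuronal activity, had 1.33 (SE 0.60), with IH 2 and IH 3 above every control and IH 1 below, and Bdnf, a growth factor of synapses, 0.30 (SE 0.10), with 3 of 3 IH libraries above every control. All 8 had adjusted p of 0.892 or more.

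The comparison within neurons asked which neuron classes respond. The genes with the smallest p were of unlike functions, and none passed. Tmsb10, which binds free actin, came up in both dentate and inhibitory neurons. In dentate granule neuron-like nuclei Luzp2 had a log2 fold of 0.85 (SE 0.14), Tmsb10 0.94 (SE 0.19) and Mal, a myelin lipid-raft protein, 0.54 (SE 0.11). In CA1 pyramidal neuron-like nuclei Lrtm1 had -0.87 (SE 0.18), Inhba, an activin subunit induced by synaptic activity, -0.54 (SE 0.12), and Mei4 0.43 (SE 0.10). In CA2/CA3 pyramidal neuron-like nuclei the kinase gene Mapk4 had -0.92 (SE 0.18), the ephrin receptor gene Epha10 -0.80 (SE 0.16) and Spata31d1a -2.05 (SE 0.46). In inhibitory neuron-like nuclei Tmsb10 had 0.83 (SE 0.15), the kinetochore gene Spc24 -2.11 (SE 0.42) and the vesicular glutamate transporter gene Slc17a8 0.81 (SE 0.18). In subicular or cortical excitatory neuron-like nuclei Cped1 had -1.18 (SE 0.22), Rpl31 1.19 (SE 0.23) and Cyr61, a matrix protein gene induced with immediate early genes, 2.86 (SE 0.56). In immature neuron-like nuclei Reln, which guides migrating neurons, had 2.09 (SE 0.43), Nrxn3 0.92 (SE 0.19) and Rpl41 0.93 (SE 0.21). In Cajal-Retzius-like nuclei Galntl6 had -2.11 (SE 0.42), Nrxn3 -1.28 (SE 0.30) and Sez6l2 -1.07 (SE 0.26). Several of these genes were among the 10 strongest of clusters of other classes, namely Mal of an oligodendrocyte-like, Cped1 of the fibroblast-like, Reln of the Cajal-Retzius-like and Galntl6 of the CA1 cluster. Each named gene except Galntl6 had its 3 IH libraries on one side of all controls, and adjusted p was 0.267 or more. The genes were picked by smallest p, so the lack of overlap is not separate support. edgeR called 0 genes in each class, against unadjusted counts of 549 of 15098 genes in dentate, 515 in CA1, 446 in CA2/CA3, 467 in inhibitory, 604 in subicular, 392 in immature and 130 in Cajal-Retzius nuclei. Without control 1, 554 genes passed in dentate, 267 in CA2/CA3 and 85 in CA1 nuclei, a setting in which group and library series cannot be told apart.

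In glia and vessels the question was the same, and the genes with the smallest p were again of unlike functions. Tmsb10 recurred in oligodendrocytes and fibroblasts, and genes of the mitochondrial genome in oligodendrocytes, their precursors and microglia. The clock gene Per2 led in astrocytes. In fibroblast-like nuclei Tmsb10 had 23.05 ± 3.33 CPM in controls and 71.2 ± 15.02 in IH (mean ± SD, n = 3 per group), a log2 fold of 1.62 (SE 0.24, adjusted p 0.0776), and the ubiquitin ligase gene Rnf220 a fold of -1.14 (SE 0.17, adjusted p 0.0776), followed by Ptma at 1.07 (SE 0.18). In astrocyte-like nuclei Per2 had 0.79 (SE 0.14), the chloride channel gene Ano1 -1.74 (SE 0.30) and Gpr179 -2.58 (SE 0.45), each with adjusted p 0.191. In oligodendrocyte-like nuclei Tmsb10 had 1.09 (SE 0.16), mt-Nd4l 1.26 (SE 0.19) and the phosphatase gene Ptpro 0.92 (SE 0.16). In oligodendrocyte precursor-like nuclei mt-Co1 had 1.08 (SE 0.22), Rplp1 0.81 (SE 0.17) and the cell-cycle kinase gene Cdk6 1.03 (SE 0.22). In newly formed oligodendrocyte-like nuclei Cnmd had -1.09 (SE 0.26), Cst3 0.79 (SE 0.19) and Galntl6 -2.72 (SE 0.68), a fold carried by control 1 at 429 CPM against 16.4 to 34.2 in the other libraries. In microglia-like nuclei mt-Co1 had 0.56 (SE 0.10, adjusted p 0.124), the growth factor gene Ptn 0.60 (SE 0.12) and Rpl17 0.67 (SE 0.14). In endothelial-like nuclei Adgrl3 had 0.94 (SE 0.23), Erbb4 -1.05 (SE 0.26) and Uba6 0.96 (SE 0.24). In nuclei of pericyte or smooth muscle type the contractile genes Myh11 and Tpm1 had -0.86 (SE 0.17) and -0.75 (SE 0.15), and Ctnna3 -0.82 (SE 0.16). In ependymal-like nuclei the thyroid hormone receptor gene Thrb had -0.96 (SE 0.19), Rps23 1.99 (SE 0.42) and Plekhh1 2.36 (SE 0.51). Plekhh1 and Rnf220 were among the 10 strongest genes of the oligodendrocyte-like cluster, Erbb4 of inhibitory neuron-like, Ptpro of immature neuron-like and Cst3 of microglia-like clusters. Oligodendrocyte markers had a median log2 fold of 0.74 in ependymal-like and 0.31 in fibroblast-like nuclei. Rnf220, lower in IH in fibroblast-like nuclei, went opposite to these markers there. On GRCm38, Tmsb10 lies on chromosome 6 from 72957347 to 72958748, Rnf220 on chromosome 4 from 117271463 to 117497052 and Per2 on chromosome 1 from 91415982 to 91459324. With edgeR 0 genes passed in each class. Chance alone gives an unadjusted p under 0.05 to a share near 0.05 of the genes tested. Such a p was found for 666 of 11921 genes in oligodendrocyte, 754 of 13037 in astrocyte and 743 of 10201 in microglia nuclei. The counts were 553 of 9410 in precursor, 280 of 6338 in newly formed oligodendrocyte and 722 of 10189 in fibroblast nuclei. They were 212 of 8065 in endothelial, 340 of 4579 in pericyte and 497 of 6610 in ependymal nuclei. Summed over all 16 classes DESeq2 called 29, 17 of them in fibroblast-like nuclei, and the replicate block gave 93 calls, 72 of them in fibroblast-like nuclei. No filter on low counts gave 830, of which 110 were genes the filter removed. Leaving out control 1, 2 or 3 gave 1070, 14 or 4 calls and leaving out IH 1, 2 or 3 gave 36, 6 or 12. Group and library series cannot be told apart without control 1, and likewise without IH 3.

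The next comparison asked whether known groups of genes moved together where single genes did not pass. Ribosomal protein, mitochondrially encoded and nuclear-encoded oxidative phosphorylation transcripts were called higher in IH in the most comparisons. Cholesterol synthesis and immediate early genes were higher in fewer, the latter mostly in neurons. These calls rest on camera's preset correlation of 0.01, under which 88 of 318 pairs of list and class passed, 77 higher and 11 lower in IH. With an estimated correlation 0 pairs passed, with adjusted p from 0.569 to 0.84 for the 88, and fry called 0. No list member passed edgeR over all genes tested. The median of none of the called pairs changed sign with RLE size factors, under which the median of all genes moved by at most 0.00619. Without each library in turn 67 to 98 pairs passed, and 46 of the 88 kept their call each time. In the other splits of the 6 libraries into 3 and 3, which mix the groups, 45 to 88 pairs passed.

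Transcripts of the cytosolic ribosome, the machine that makes proteins, were higher in 15 of 17 comparisons. In the other splits of the 6 libraries into 3 and 3 this list was called in 6 to 14 comparisons. The difference between IH and control was largest in ependymal cells and fibroblasts and reached astrocytes, neurons and the oligodendrocyte lineage, while pericytes and Cajal-Retzius cells were not called. In ependymal-like nuclei 43 of 44 members were higher, with a median log2 fold of 0.90 and 29 members past the threshold when adjusted over the list alone, against 0 over all genes tested. In fibroblast-like nuclei 49 of 49 were higher, with a median of 0.84 and 35 adjusted over the list alone. In astrocyte-like nuclei 49 of 49 were higher, with a median of 0.42 and 27 adjusted over the list alone, and Rpl3 had a log2 fold of 0.69 (SE 0.16). Oligodendrocyte-, microglia- and precursor-like nuclei had medians of 0.30, 0.32 and 0.40, with 14, 12 and 9 members adjusted over the list alone. Ribosomal-protein-rich clusters of astrocyte-, oligodendrocyte- and microglia-like nuclei had been kept apart by the same transcripts that were tested here. The results in these classes therefore hold for the remaining nuclei only. With the ribosomal-protein-rich clusters merged in, the microglial direction reversed (adjusted p 0.152). Dentate granule neuron-like nuclei had a median of 0.37 with 49 of 49 members higher, and all kept nuclei 0.16 with 47 of 49. With the estimated correlation the adjusted p was 0.569 in these classes and 0.8 in all kept nuclei. The call in all kept nuclei ended without IH 3 (adjusted p 0.591) and without control 3 (0.0827), that in endothelial-like nuclei ended without IH 1 (0.437) and without control 2 (0.302), and the other 13 held without each library. Within the plain-prefix pair the ribosomal median was 0.46 in ependymal-like, 0.34 in fibroblast-like and 0.23 in astrocyte-like nuclei, but -0.01 in dentate, -0.03 in CA1 and -0.02 in CA2/CA3 nuclei. In the Q-prefix libraries it was 0.93, 1.08, 0.52, 0.52, 0.44 and 0.35 in the same order.

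Markers of oligodendrocytes were higher outside their own lineage as well, in 9 of 12 comparisons, and lower in endothelial-like nuclei. These lists of other cells formed a family of their own, with 24 of 73 pairs called. The oligodendrocyte markers had a median log2 fold of 0.24 in dentate, 0.31 in CA1, 0.28 in inhibitory and 0.74 in ependymal nuclei, and over all their calls adjusted p for the estimated correlation was 0.355 to 0.613. Markers of astrocytes were higher in 5 of 12 comparisons, with a median of 0.52 in microglia-like nuclei and an adjusted p for the estimated correlation of 0.355 to 0.398. Markers of choroid plexus were lower in 7 of 9, with a median of -1.08 in all kept nuclei and -1.10 in astrocyte-like nuclei and an adjusted p for the estimated correlation of 0.355 to 0.46. IH 2 and IH 3 lacked nuclei in the main choroid plexus cluster and IH 1 held them. These medians therefore do not stand for each IH library. Thalamus markers were lower in all kept nuclei, with a median of -0.27 and an adjusted p for the estimated correlation of 0.355. Red blood cell genes were lower in astrocyte-like nuclei, with a median of -1.58 and an adjusted p for the estimated correlation of 0.493, but Hbb-bs stood at 449 CPM in control 2, at 161 in IH 3 and at 0.979 to 22.9 in the other libraries. Cortex and dentate granule markers were called in 0 comparisons, and sex-linked genes also in 0.

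Mitochondrially encoded transcripts, which encode core parts of the respiratory chain, were higher in 12 of 17 comparisons. They are made in mitochondria and not in the nucleus, and the libraries are of nuclei. A change of respiratory-chain expression within IH cells was therefore not tested by them. The largest difference was in oligodendrocyte precursors. In precursor-like nuclei 11 of 11 members were higher, with a median log2 fold of 1.00 and 11 adjusted over the list alone, and mt-Co2 had a log2 fold of 1.17 (SE 0.26). Fibroblast-like nuclei had a median of 0.81, ependymal-like 0.50, astrocyte-like 0.47 and dentate granule neuron-like 0.47. The dentate result reversed without IH 1 (adjusted p 0.35) and its call ended without control 2 (0.0725), and 6 of the 12 calls held without each library. IH 1 stood apart with the highest mitochondrial share of UMIs, and without it the calls also ended in all kept (0.266), astrocyte-like (0.109) and immature neuron-like nuclei (0.576) and reversed in newly formed oligodendrocyte-like nuclei (0.964). The adjusted p with the estimated correlation was 0.569 in precursors and at most 0.72 in the others. The nuclear-encoded genes of oxidative phosphorylation were higher in 10 of 17 comparisons, with medians from 0.09 in oligodendrocyte- to 0.35 in fibroblast-like nuclei and adjusted p for the estimated correlation of 0.569 to 0.84. The oligodendrocyte result reversed without control 1 (0.991) and with ribosomal-protein-rich clusters merged (0.459), its call ended without IH 1 (0.423) or IH 3 (0.0941), and 4 of the 10 calls held without each library. In precursor-like nuclei the mitochondrial genes lay above every control in 2 of 3 IH libraries for mt-Co1, at 421 CPM in the remaining one against 473 in control 1. With the 3-level series term, which rests on control 1 against IH 3, mitochondrially encoded genes were lower in IH in dentate, astrocyte-, precursor- and immature neuron-like nuclei, with adjusted p of 0.0065, 0.0065, 0.00577 and 4.11e-07.

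Immediate early genes, which neurons switch on within minutes of activity, were higher in all kept nuclei, in 5 classes of mature neurons and in fibroblasts. The difference was largest in subicular or cortical excitatory neurons. Genes that tissue dissociation induces were higher in the same neuron classes. In subicular nuclei 19 of 19 immediate early genes were higher, with a median log2 fold of 0.89 and 11 adjusted over the list alone. There Arc, which acts at active synapses, had a log2 fold of 2.18 (SE 0.58), Egr1 1.90 (SE 0.49), Egr3 1.75 (SE 0.47) and Junb 1.61 (SE 0.44), each above every control in 2 of 3 IH libraries. The median was 0.52 in inhibitory, 0.50 in CA1, 0.38 in dentate and 0.21 in CA2/CA3 nuclei, with adjusted p for the estimated correlation of 0.569 to 0.771. Over neuron nuclei the mean log2 CPM of the list was 2.75, 2.37 and 2.80 in controls 1 to 3 and 2.60, 2.99 and 3.29 in IH 1 to 3. The dissociation list, which shares 9 of its 26 members with this list and 6 with heat shock proteins, passed higher in 6 comparisons, with a median of 0.40 in subicular nuclei, and lower in endothelial-like nuclei, with a median of -0.21. With the estimated correlation 0 of these calls passed (adjusted p 0.569 to 0.686). Of the immediate early gene calls 5 of 7 held without each library. The CA2/CA3 call ended without control 1, control 2, IH 2 or IH 3 (adjusted p 0.0517, 0.91, 0.0867 and 0.275) and the fibroblast call without control 2, control 3, IH 1 or IH 2 (0.146, 0.148, 0.0635 and 0.161), as did dissociation calls in CA1 without control 1 or IH 3 (0.0616 and 0.249) and in endothelial nuclei without control 2, control 3, IH 1 or IH 3 (0.138, 0.456, 0.311 and 0.371).

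**Figure D2:**
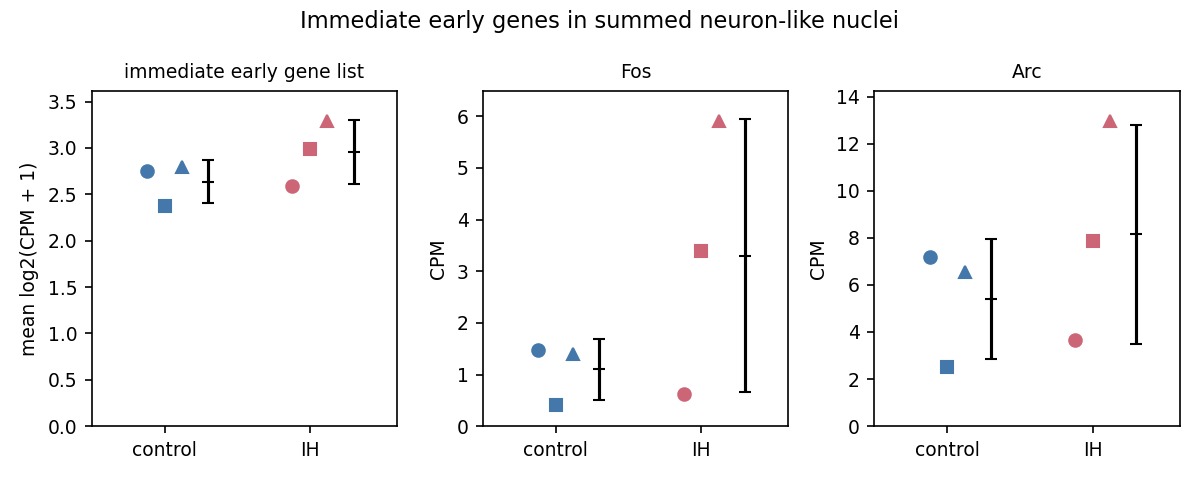
Mean log2(CPM + 1) of the immediate early gene list, and CPM of Fos and Arc (vertical axes), in summed neuron-like nuclei, with a point per library and the mean ± SD of each group. IH 1, at 2.60 for the list, lies among the controls, and IH 2 and IH 3 lie above them.

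Genes of cholesterol synthesis, which supply membranes and myelin, were higher in all kept nuclei, in 5 of the neuron classes, and in astrocytes and microglia. In astrocyte-like nuclei 21 of 21 members were higher, with a median log2 fold of 0.40 and 0 adjusted over the list alone. There Sqle had a log2 fold of 0.56 (SE 0.17), Sc5d 0.40 (SE 0.13) and Hsd17b7 0.60 (SE 0.19). In all kept nuclei 22 of 22 were higher, with a median of 0.23. The adjusted p with the estimated correlation was 0.569 in both and at most 0.8 in the other classes. With the 3-level series term the list was lower in IH in astrocyte-like nuclei (adjusted p 0.0119). Its direction also reversed under this term in CA1, microglia-like, inhibitory and CA2/CA3 nuclei, where it was not called. The call held without each library in 4 of 8 comparisons and ended in CA1 nuclei without control 2, control 3, IH 1 or IH 3 (adjusted p 0.56, 0.169, 0.0635 and 0.131), in microglia without control 2, IH 1 or IH 2 (0.147, 0.0763 and 0.0715), in inhibitory neurons without control 2 (0.171) and in subicular nuclei without control 2 or IH 3 (0.106 and 0.202).

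Clock genes, which keep daily time, were called in 5 comparisons, and some members had opposite signs in glia. The endothelial call ended without control 2, control 3 or IH 2 (adjusted p 0.0725, 0.0974 and 0.0688), and the other 4 held without each library. In astrocyte-like nuclei Per2 and Nr1d2 had log2 folds of 0.79 (SE 0.14) and 0.41 (SE 0.13), whereas their activators Arntl and Npas2 had -0.56 (SE 0.14) and -0.48 (SE 0.15). In oligodendrocyte-like nuclei Dbp had 1.13 (SE 0.30), Nr1d2 0.55 (SE 0.15), Cry2 0.47 (SE 0.14) and Arntl -0.64 (SE 0.17). Adjusted over the list alone, 9 members passed in astrocyte-like nuclei, 7 higher and 2 lower, and 7 passed in oligodendrocyte-like nuclei, 6 higher and 1 lower. The list median was 0.10 and 0.42 in these classes, and the adjusted p with the estimated correlation was 0.569. For each of these member values all 3 IH libraries lay on one side of every control. The members were picked by smallest p, so this is not separate support.

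The remaining lists asked about low oxygen, stress, inflammation and synapses. Targets of HIF, the factor that low oxygen stabilizes, were called in 0 of 16 comparisons, with medians from -0.03 to 0.10, and adjusted p of 0.143 or more. Among them Car9 had a log2 fold of -0.89 (SE 0.27) and Tfrc 0.27 (SE 0.10) in all kept nuclei. Glycolysis was higher in 3 comparisons, namely microglia-, subicular and precursor-like nuclei, with medians from 0.13 to 0.20. The oxidative stress response was higher in 3, heat shock proteins in 4, and autophagy and lysosome genes in 2, of which 1, 2 and 1 held without each library, with adjusted p of up to 0.203, 0.975 and 0.168 in the rest. The glucocorticoid response was called in dentate nuclei, with a median of 0.20, while medians reached 0.41 in classes without a call, and the difference between classes was not tested. The unfolded protein response was lower in all kept, oligodendrocyte- and precursor-like nuclei, with a median of -0.37 in the last, and higher in fibroblast-like nuclei. Of these 4 calls only that in precursors held without each library, and adjusted p reached 0.422 in all kept and 0.4 in oligodendrocyte-like nuclei without IH 2 and 0.617 in fibroblast-like nuclei without IH 1. Interferon response genes were lower in all kept nuclei, 25 of 25 members with a median of -0.26, and the cytokine and NF-kB response in all kept and microglia-like nuclei, with a median of -0.17 in each. The interferon list was called in 1 of 12 comparisons, so no cell class was called, and medians reached 0.21. A sum over all kept nuclei also moves with the mix of classes, and this was not tested. The cytokine call ended without control 1 or IH 1, both in all kept nuclei (adjusted p 0.99 and 0.349) and in microglia (0.0633 and 0.138), and the interferon call without control 1 (0.365). Reactive astrocyte genes were lower in astrocyte-like nuclei, 14 of 16 members with a median of -0.24, and neurogenesis genes in immature neuron-like nuclei, 15 of 16 with a median of -0.22. The former call ended without control 1 (adjusted p 0.169) and the latter without IH 2 (0.252). Oligodendrocyte differentiation genes were lower in precursors, with a median of -0.13 (10 of 14 members), and glutamate receptor genes in Cajal-Retzius-like nuclei, with -0.15. None of the glycolysis, glucocorticoid, differentiation and glutamate receptor calls held without each library, with adjusted p of up to 0.56, 0.271, 0.228 and 0.676. Called in 0 comparisons were apoptosis and p53 targets, presynaptic release genes, GABA receptor genes, potassium and sodium channels, myelin genes, astrocyte transport, homeostatic microglia, disease-associated microglia, and angiogenesis and blood-brain barrier genes. With the estimated correlation the adjusted p of every call in this group was 0.569 or more.

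**Figure D3:**
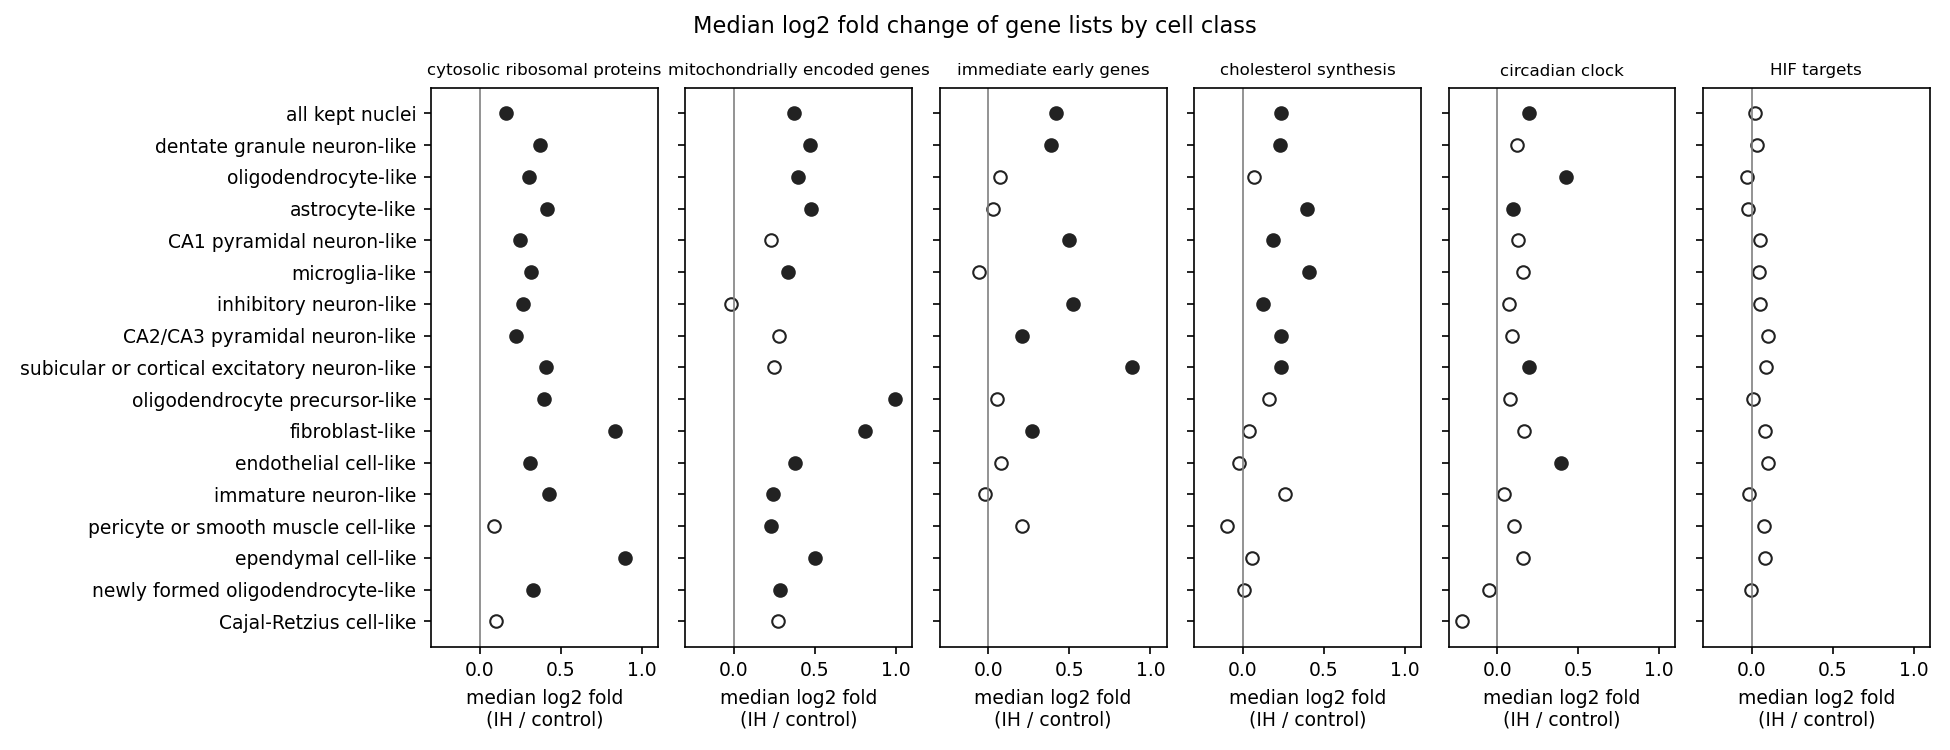
Median log2 fold (IH over control, horizontal axes) of 6 gene lists, with a point for all kept nuclei and for each cell class. Filled points passed camera at its preset correlation, and the ribosomal medians lie between 0.09 and 0.90.

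The last comparison asked whether the condition effect itself differs among cell classes, which separate calls per class cannot show. By the interaction test 7 of 15604 genes passed. edgeR gave 827 genes an unadjusted p under 0.05, which chance alone gives to a share near 0.05 of the genes tested. Rspo2, a Wnt-enhancing secreted protein gene, had an interaction F of 4.99 (adjusted p 0.0146), with log2 folds of 0.98 in fibroblast-like and -0.52 in subicular nuclei. Colec12, a scavenger receptor gene, had an F of 4.33 (adjusted p 0.0282), with -1.99 in ependymal-like and 0.82 in precursor-like nuclei. It was among the 10 strongest genes of the fibroblast-like cluster, where its fold was -0.10 and whose mean share was lower in IH, and it also had -1.38 in subicular and -1.17 in CA2/CA3 nuclei. Rarb, a retinoic acid receptor gene, had an F of 4.33 (adjusted p 0.0282), with 1.08 in oligodendrocyte-like and -0.73 in CA1 nuclei. Fam19a4, a secreted peptide gene, had an F of 4.28 (adjusted p 0.0282), with -1.95 in dentate and 0.13 in precursor-like nuclei. Pde10a, a phosphodiesterase gene prominent in striatal neurons, had an F of 4.25 (adjusted p 0.0282), with -2.08 in astrocyte-like and 1.30 in Cajal-Retzius-like nuclei. Sntg2 had an F of 4.24 (adjusted p 0.0282), with 0.84 in dentate and -0.69 in subicular nuclei, and Mdfic an F of 4.16 (adjusted p 0.0351), with -1.79 in dentate and 0.19 in endothelial-like nuclei. On GRCm38, Rspo2 lies on chromosome 15 from 43020794 to 43170826, Colec12 on chromosome 18 from 9707595 to 9882644, Rarb on chromosome 14 from 16430839 to 16819156 and Pde10a on chromosome 17 from 8525372 to 8986648. Without control 1, 2 or 3 the count of genes was 373, 0 or 1, and without IH 1, 2 or 3 it was 8, 3 or 0. Group and library series cannot be told apart without control 1, and likewise without IH 3. With no filter on low counts the count was 531. Of the 10 splits of the libraries into 3 and 3, the real one included, 6 gave at least 7 genes.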

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

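Of the tests here, the 10 splits for the interaction and for gene lists and the comparison of ribosomal medians between library series were set beforehand, although ribosomal shares per library had been seen by then, and the tests on free RNA, tissue handling, single IH libraries, dissection and the splits for single genes were chosen only after the result was seen.

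The condition effect differed among cell classes for 7 genes by the interaction test, which is what singled them out. Rspo2 had an interaction F of 4.99, with a log2 fold of 0.98 in fibroblast-like and -0.52 in subicular nuclei. Colec12 had an F of 4.33, Rarb 4.33, Fam19a4 4.28, Pde10a 4.25, Sntg2 4.24 and Mdfic 4.16. Fam19a4 had a negative log2 fold in each of the 5 mature neuron classes, from -1.95 in dentate to -1.44 in CA2/CA3 nuclei, and stood at 0.13 in precursor-like nuclei. Of the 10 splits of the 6 libraries into 3 and 3, 6 gave 7 or more genes, and the highest other count was 283. That split set control 1, IH 1 and IH 3 against the rest, which points to a structure of the samples, and 10 splits are too few for a share under 0.05. Leaving out control 1, 2 or 3 gave 373, 0 or 1 genes and leaving out IH 1, 2 or 3 gave 8, 3 or 0, so these 7 genes are leads that rest on particular libraries.

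Ribosomal protein transcripts were higher in IH in 15 of 17 comparisons by camera and in 0 with the estimated correlation (adjusted p 0.569 to 0.8). The other splits of the libraries gave 6 to 14, and 10 splits are too few for a share under 0.05. In astrocyte-, oligodendrocyte- and microglia-like nuclei, clusters rich in these same transcripts had been kept apart. Merging those clusters in reversed the microglial direction. If free RNA from other cells were the source, the ribosomal median should have stayed at or below that of oligodendrocyte markers. It lay above in 7 of 12 classes, for instance in endothelial-like nuclei at 0.31 against -0.26, and below in immature neuron-like nuclei at 0.43 against 0.57, so free RNA from other cells and a change within the cells cannot be told apart, because neither outcome was general. The library name series gave a median above 0 in both the plain-prefix pair and the Q-prefix libraries in 10 of 14 called classes, between the limits set beforehand. Dentate, CA1, CA2/CA3 and immature neurons did not keep their direction in the plain-prefix pair, the median there was only 0.03 in newly formed oligodendrocyte-like, 0.05 in inhibitory and 0.06 in subicular nuclei, the first of these reversed with the 3-level series (adjusted p 0.963), and a change of protein synthesis in IH cells remains untested.

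Immediate early genes were higher in IH neurons by camera, most in subicular or cortical excitatory nuclei, and 0 of these calls passed with the estimated correlation (adjusted p 0.569 to 0.771). Dissociation genes outside the list had a median above 0 in 5 of 5 called neuron classes, which is consistent with tissue handling that differed between the libraries, but medians of 0.33 in precursor-like and 0.45 in ependymal-like nuclei, where immediate early genes were not called, mean that this test does not single out those neurons. In the mean of the list over neuron nuclei 2 of 3 IH libraries lay above every control, and IH 1 at 2.60 lay among them, so fewer than 3 IH libraries carry the difference. Neuronal activity raised by the IH condition may act as well, and no value here separates it from handling.

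Ependymal nuclei were fewer in IH, 0.614% against 1.22%. Choroid plexus and fibroblast nuclei, taken as neighbours along the ventricle, also had lower mean shares in IH in 2 of 2 classes (exact p 0.3 for each), so dissection or the ventricle wall included stays a candidate explanation. The libraries did not follow it throughout, since IH 1 held 2.25% choroid plexus nuclei, above 2 of 3 controls, at an ependymal share of 0.533%, and IH 2 held 0 in the main choroid plexus cluster at an ependymal share of 0.851%. The fibroblast share of IH 2, at 2.68%, lay within the control range, and the strongest genes of that cluster, such as Slc6a13 and Aldh1a2, are known from the meninges, so its place beside the ventricle is assumed. The unnamed cluster with thalamic markers also held fewer barcodes in each IH library than in any control. Thalamus markers were lower in all kept nuclei by camera, though not with the estimated correlation. These values bear on the tissue taken as well and were not part of this test. Loss of ciliated cells in IH stays open and was not tested.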

How the results depend on the processing

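Alternatives chosen only after the result was seen were robust moderation, sex, the 3-level series, merged ribosomal-protein-rich clusters and other denominators, and the tests under the rest were planned. Over all kept nuclei DESeq2 called 82 genes and the 3-level series term 7, leaving out 1 library gave 0 to 141, and every other setting run gave 0. Summed over the classes DESeq2 called 29 genes, no filter on low counts 830, the library name series 10, the 3-level series 30, sex as a term 12, robust moderation 3 and Leiden resolution 0.5 2, and leaving out 1 library gave 4 to 1070, while RLE factors, doublets kept, stricter nuclei filters, equal nuclei, merged clusters and a fold of at least 1.5 gave 0. Without a filter 110 of the 830 genes were ones the filter removed. With the replicate number as a block 93 genes passed, 72 of them in fibroblast-like nuclei. Called list pairs fell from 88 to 0 with the estimated correlation and to 0 with fry, and leaving out 1 library gave 67 to 98. The series, 3-level series, sex, block and merged settings gave 85 to 92. Of the 85 pairs under the 3-level series only 37 were among the main 88. Under that term 22 were lower in IH, against 11 in the main test. The series, sex, block and merged settings shared 83 to 85 with the main 88. Classes without overlap went from 4 to 2 with shares of named classes without choroid plexus, ependymal and fibroblast nuclei, and to 2 with at least 1000 detected genes, and leaving out 1 library gave 4 to 6, where chance gives 20%. The interaction count went from 7 to 531 with no filter and to between 0 and 373 with 1 library left out. UMIs and genes per nucleus kept their direction in the settings run, except the thinned genes, whose small difference of 2.67 went to -0.667 without IH 3. Median genes lost their overlap with at most 2% mitochondrial UMIs (exact p 0.1) and without control 3 or IH 3, and without IH 2 their difference went from -159 to -64.8 and that of UMIs from -382 to -131. The cause was not tested for any of these.

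The direction of 33 list results reversed under an alternative, given here as the adjusted p of the reversed result, and the cause was not tested. Without control 1 these were cytokines in all kept nuclei (0.99) and oxidative phosphorylation in oligodendrocyte-like nuclei (0.991), and without control 3 mitochondrially encoded genes in immature neurons (0.905). Without IH 1 they were mitochondrially encoded genes in dentate (0.35) and newly formed oligodendrocyte nuclei (0.964) and ribosomal proteins in endothelial nuclei (0.437). Without IH 2 it was heat shock proteins in ependymal nuclei (0.975), and without IH 3 ribosomal proteins in all kept nuclei (0.591). With merged clusters they were oxidative phosphorylation in oligodendrocyte (0.459) and ribosomal proteins in microglia-like nuclei (0.152). With the 3-level series, which rests on control 1 against IH 3, mitochondrially encoded genes reversed in dentate (0.0065), astrocyte (0.0065), precursor (0.00577), immature (4.11e-07), pericyte (0.984) and newly formed oligodendrocyte nuclei (0.26). Ribosomal proteins reversed there in CA1 (0.259), CA2/CA3 (0.232), immature (0.673) and newly formed oligodendrocyte nuclei (0.963), and cholesterol synthesis in astrocyte (0.0119), CA1 (0.101), microglia (0.405), inhibitory (0.488) and CA2/CA3 nuclei (0.153). Also reversed were oxidative phosphorylation in dentate (0.958), inhibitory (0.264) and subicular nuclei (0.232), the unfolded protein response in all kept (0.656) and oligodendrocyte nuclei (0.831), glycolysis in microglia (0.896), differentiation genes in precursors (0.984) and immediate early genes in fibroblasts (0.697). Over the libraries left out in turn the adjusted p of these results ranged from 0.00123 to 0.99 for cytokines in all kept nuclei, from 5.26e-07 to 0.991 for oxidative phosphorylation in oligodendrocyte nuclei, from 4.02e-15 to 0.591 and 1.02e-25 to 0.437 for ribosomal proteins in all kept and endothelial nuclei, from 0.000544 to 0.975 for heat shock proteins in ependymal nuclei, and from 5.42e-07 to 0.35, 6.05e-11 to 0.905 and 3.33e-07 to 0.964 for mitochondrially encoded genes in dentate, immature and newly formed oligodendrocyte nuclei. Of the other list results 797 kept direction and side of the threshold and 314 kept direction alone. Values of named genes kept direction and stayed short of the threshold in 1037 cases and passed it in 103. Another 8 moved, 7 of them Epas1 and the other mt-Co1 in precursors. Most of these genes were picked by smallest p, which makes a kept direction likely, so this tally is not separate support. Shares of nuclei were judged by another rule, namely a difference within the larger group SD of the main one, whatever its sign. For the edgeR test on nuclei counts the rule was the same sign without a call. By these rules 204 cases stayed and 1 moved, that of immature neurons with at least 1000 detected genes (difference 0.214 against 0.412 points). Resolution 0.5 left astrocytes unnamed, so that class has no value there. Shallow classes limit what could be seen, since 2-fold changes were recovered for 32 of 67 simulated genes in ependymal and 24 of 67 in endothelial nuclei.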

Other observations

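The tests in this part on splits of the samples were chosen after the result was seen for single genes and beforehand for gene lists. Some clock genes of glia had fold changes of opposite sign. In astrocyte-like nuclei Per2 had 34.3 ± 3.89 CPM in controls and 59.5 ± 6.43 in IH (mean ± SD, n = 3 per group), while Arntl had 186 ± 31.1 and 126 ± 17. Arntl drives Per2 and Nr1d2, and the product of Nr1d2 in turn holds Arntl down. The same signs held in oligodendrocyte-like nuclei, where Dbp had 3.3 ± 0.414 and 7.3 ± 1.51 CPM and Arntl 40.1 ± 6.88 and 25.7 ± 3.98. Per2 and Arntl had no overlap between the groups in astrocyte-like nuclei, but they were named for their small p, so this is not separate support. Neither passed over all genes tested. The labels give no time of day for tissue collection.

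Free RNA of choroid plexus was nearly missing from IH 2 and IH 3, the libraries without nuclei of that class outside the ribosomal-protein-rich cluster. Ttr, the transthyretin gene and its most abundant marker, stood in dentate granule neuron-like nuclei at 144, 22.1 and 75.6 CPM in controls 1 to 3, at 96.2 in IH 1, and at 0.0881 and 0.265 in IH 2 and IH 3. In CA1 nuclei Ttr stood at 0 in IH 2 and at 0.142 CPM in IH 3. Ttr in dentate nuclei stood above 1 CPM only in the 4 libraries with nuclei in the main choroid plexus cluster.

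Tmsb10 was among the 3 genes with the smallest p in 4 classes. Its log2 fold was 1.62 (SE 0.24) in fibroblast-like, 1.09 (SE 0.16) in oligodendrocyte-like, 0.94 (SE 0.19) in dentate and 0.83 (SE 0.15) in inhibitory neuron-like nuclei. In each of these classes all 3 IH libraries lay above every control, which its choice by smallest p makes likely. In none did it pass, with adjusted p from 0.0776 to 0.9995. Tmsb10 is a short transcript, as are those of ribosomal proteins.

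Hemoglobin transcripts differed widely between libraries of the same group. In astrocyte-like nuclei Hbb-bs stood at 12.7, 449 and 22.9 CPM in controls 1 to 3 and at 0.979, 2.43 and 161 in IH 1 to 3. The log2 fold of Hbb-bs was -1.58 there, -7.37 in oligodendrocyte-like, -6.29 in CA1 and -3.43 in subicular nuclei, that of Hba-a1 was -6.62 in oligodendrocyte-like nuclei, and neither gene passed the interaction test (adjusted p 0.163 and 0.228).

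The features include cre and tdTomato, a recombinase and a fluorescent reporter, which mice carry only as transgenes. In kept nuclei cre had 541, 352 and 268 counts in controls 1 to 3 and 242, 267 and 270 in IH 1 to 3, and tdTomato 16, 39 and 25 against 37, 38 and 26. No label mentions a transgenic strain.

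Clusters rich in ribosomal protein transcripts, and kept apart from their classes, had shares that varied between libraries. The microglial ones made up 1.64% ± 1.84 of control and 1.29% ± 1.68 of IH nuclei (mean ± SD, n = 3 per group), the oligodendrocyte ones 2.23% ± 1.85 and 1.52% ± 1.64, the astrocyte ones 0.547% ± 0.411 and 0.544% ± 0.175, and the choroid plexus ones 0.103% ± 0.0828 and 0.103% ± 0.0625. Unnamed nuclei made up 15.6% ± 1.12 and 16.2% ± 4.35.

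For genes over all kept nuclei the real split gave 0 and the highest other count was 0. Summed over the 16 classes the real split gave 0 and the highest other count was 320, from control 1, IH 1 and IH 3 against the rest. With a real count of 0 each of the 10 splits gives as many, so that tally tests nothing. A split with many more calls than the real one points to a structure of the samples. For gene lists the real split gave 88 pairs, 2 of 10 splits gave as many, and the highest other count was 88, from control 1, IH 2 and IH 3 against the rest. With 10 splits a share under 0.05 cannot be reached in any of these.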
